A study of Mus musculus with 1376 samples.

How the data were processed

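The series holds single cells from dissociated lung of ACTA2GFP:CSPG4dsRED mice, a strain whose name gives fluorescent reporters for smooth muscle actin (Acta2) and for the proteoglycan NG2 (Cspg4). Per the labels' protocols, cells were sorted one per well into 384-well plates and made into libraries by Smart-Seq2, a method that reads full-length cDNA and adds no molecular identifiers. The gate used in the sort is not given in the sources used here. Each deposited sample is 1 cell. The labels name 3 mice, namely male mouse 1 (653 cells on plates 045s and 046s), male mouse 2 (352 cells on plate 131s) and female mouse 1 (371 cells on plate 505s). The sample labels give an age of 8 to 30 weeks and the series description one of 8 to 21 weeks, and the description speaks of male mice although 1 mouse is labelled female. The extract protocol names heart, with a kit for skeletal muscle, while the tissue label says lung.

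The deposited table holds whole-number read counts per gene and cell, per the file headers and the values themselves. The submitters' processing notes name bcl2fastq, Bowtie, Bowtie2, featureCounts and Subread and the builds GRCm38 and mm10, with no versions, roles or order. The treatment of strand, multi-mapping reads and duplicate reads is not given in the sources used here, so a gene cannot be told from an overlapping or antisense neighbour, and members of families with shared sequence are uncertain. No gene longer than 200 exonic bases passed 1.92 counts per exonic base in any cell. The table has 46517 Ensembl genes. Of these, 46005 took a symbol from the GENCODE M21 annotation of GRCm38, which also gave the coordinates, and 512 kept their identifier and held 0.184% of all counts. No column was left unused, and no cell had the same counts as another.

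Counts per cell ran from 50835 to 1074103, with a median of 230688, and genes with a count per cell from 1519 to 9734. Mitochondrial genes took 0.114% to 14.1% of a cell's counts. The cell filter of at least 1000 genes, 20000 counts and at most 20% mitochondrial counts removed 0 of 1376 cells. The deposited cells thus all lay above that filter, and whether they had been filtered earlier is not given in the sources used here. A stricter filter of 2000 genes and 100000 counts kept 1193 cells. No doublet caller was run, and cells with markers of more than 1 class were not removed one by one.

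Cells were clustered with code written for this data on numpy, scikit-learn, igraph and leidenalg (counts scaled to 10000 per cell, natural log of 1 plus that value, 2000 variable genes, 30 principal components, a graph of 15 nearest neighbours weighted by shared neighbours, Leiden resolution 1, seed 1, no batch correction). Clusters took a name ending in -like from marker genes fixed before the data were examined, together with the gene lists, the tests and most alternatives. The scoring rule was set after the clusters had been seen. It asked for 3 markers of a class each detected in at least 25% of cells and for a margin of 0.25 over the next class in mean scaled expression. It looked at the 10 leading genes with at least 16 CPM (the usual unit of counts scaled to library size) for markers of other classes. In the clustering on all variable genes, that margin kept out a cluster of 71 cells with fibroblast markers of more than 1 class. This cluster made up 4.13% of the cells of male mouse 1, 5.11% of male mouse 2 and 7.01% of female mouse 1.

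Testing genes between clusters that the same genes define would overstate differences. Genes were therefore split at random into 2 parts of equal size (seed 1). Cells were clustered on the 1000 most variable genes of one part and named with markers of both. Genes of the other part were tested between those classes, and the parts then swapped. This lowers the dependence on the clustering and does not remove it, as genes of both parts vary together. The 2 clusterings had an adjusted Rand index of 0.653, and 1148 of the 1178 cells named in both (97.5%) got the same name.

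The mouse was the replicate. Raw counts were summed per class and mouse, and a class entered the fit if it had at least 10 cells in each of the 3 mice in both clusterings. The 5 classes that did so gave 15 sums. Adventitial fibroblast-like cells had 1, 2 and 14 cells in male mouse 1, male mouse 2 and female mouse 1 in one clustering, so 2 of the 7 planned comparisons were not run. Gene tests used edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, version 4.0.16) on the sums with TMM factors, filterByExpr by class and the mouse as a block, two-sided, with Benjamini-Hochberg adjustment over the 16129 genes tested in both parts and calls at an adjusted p under 0.05. Every adjusted p of a gene below comes from this test unless another is named. Standard errors are the size of the log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, as mean ± SD over the 3 mice. Genes called include naming markers, whose number is given and which are not named as findings. Classes of the same mouse share that mouse in truth. After the class means were removed, sums of the same mouse correlated with a median r of 0.125 (0.0383 to 0.287 over 30 pairs), against −0.0786 over 60 pairs from other mice.

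Most genes named in the text followed a rule set in advance. They are the 10 with the largest fold in each direction among genes called, of the same sign in all 3 mice, with an average log2 CPM of at least 4, at least 10 cells with a count in the higher class of each mouse, no naming marker and no model name, and, called or not, up to 4 members of each list with the smallest adjusted p and counter-examples from it. Naming markers of vascular clusters were named outside this rule. Not every gene that met this rule is named, and some results are not reported here. The 13 lists were tested with limma's cameraPR at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 65 tests of 5 comparisons, and again with the correlation estimated from the residuals. Each list is described by the genes called over all genes tested and by those passing when adjusted over the list alone. List members that are naming markers were left out, and 6 list symbols had no gene of that name in the annotation. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals, and a share of 0 carries the limit that 3 cells of the total would give. Reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only.

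The gene test was run on simulated data in which 200 genes changed in 1 class and no others differed between the compared classes. Folds of 2 and 4 recovered almost no genes, and folds of 8, 16 and 32 were then added. In the comparison of airway with vascular SMC-like cells, 0 of 18 changed genes with an average log2 CPM of at least 4 were called at a fold of 2, 0 of 20 at 4, 3 of 22 at 8, 9 of 20 at 16 and 14 of 27 at 32. Of pericyte against vascular SMC-like cells, the recovered shares at folds of 8, 16 and 32 were 20.0%, 40.7% and 64.0%. Those shares were 17.9%, 34.6% and 46.9% for pericyte against airway SMC-like cells, 10.5%, 28.0% and 65.5% for alveolar myofibroblast against airway SMC-like cells, and 23.1%, 37.0% and 48.1% for alveolar fibroblast against pericyte-like cells. Unchanged genes called numbered 0 in the first 4 comparisons and 1 in the last, which tests no error from clustering. The real fit of pericyte against vascular SMC-like cells called 13 of 21 contractile genes (median log2 fold change −1.64). These shares may thus understate it. A gene not called is still not shown to be equal.

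Alternatives chosen in advance were DESeq2, RLE factors, no filter on low counts, no block, each mouse or either plate of male mouse 1 left out, only the compared classes in the fit, classes from all variable genes, another random split of the genes, other Leiden resolutions, the stricter cell filter and each cell scaled to the same total. RLE factors moved the median log2 fold change of all genes by 0.17 for airway against vascular SMC-like cells, by 0.24 for pericyte against vascular SMC-like cells and by −0.17 for alveolar fibroblast against pericyte-like cells. Comparisons among vascular clusters, and a fit without 2 vascular clusters that were shallow or came from 1 mouse, were added after the data had been seen. The tools were Python 3.11.15, numpy 2.4.6, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.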

Results

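Gene expression was measured in 1376 single cells from the lungs of 3 mice by full-length cDNA sequencing. Male mouse 1 gave 653 cells on 2 plates, male mouse 2 gave 352 on 1 plate and female mouse 1 gave 371 on 1 plate, so mouse, plate and sex cannot be told apart for the last pair. Plates 045s and 046s of male mouse 1 held 91521822 and 97633394 counts, the plate of male mouse 2 held 66873579 and that of female mouse 1 held 98841310. The median cell had 259185 counts on plate 045s, 276501 on 046s, 172579.5 in male mouse 2 and 236324 in female mouse 1. The series title concerns an inventory of smooth muscle cells (SMC), and the comparisons below ask which genes set the muscle, mural and fibroblast classes of the lung apart. Summed counts per class and mouse ran from 1812315 to 106325222.

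Sex-linked genes were looked at first as a check of the labels. Xist, the RNA of the inactive X chromosome, had 360 CPM in female mouse 1, with a count in 359 of 371 cells, against 1.85 CPM in male mouse 1 and 0.673 CPM in male mouse 2. The Y-linked gene Ddx3y had 120.1 CPM in male mouse 1, 151 CPM in male mouse 2 and 1 count in female mouse 1. Kdm5d and Uty, also Y-linked, still had 188 counts in 82 cells and 96 counts in 69 cells of female mouse 1. Across the 5 compared classes, 4 genes lay at least 4-fold outside the range of both males in every class. Xist was higher in the female mouse, and Ddx3y, Eif2s3y and the mitochondrial gene mt-Atp6 were lower, the last by a smallest fold of 5.39. The median mitochondrial share was 0.571% in female mouse 1 against 1.64% to 1.97% on other plates. That smaller gap may explain mt-Atp6 only in part. With cells scaled to the same total, 6 genes lay so far out, 3 of them shared. These values carry no test, as 1 mouse is female.

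Vascular SMC-like cells made up 54.2% of the cells of male mouse 1 (exact 95% interval 50.3% to 58.1%), 54.5% of male mouse 2 (49.2% to 59.8%) and 27.8% of female mouse 1 (23.3% to 32.6%). Airway SMC-like cells made up 6.43% (4.67% to 8.59%), 3.98% (2.19% to 6.58%) and 7.82% (5.30% to 11.03%) in the same order. Pericyte-like cells, the mural cells of capillaries, made up 2.91% (1.76% to 4.51%), 3.69% (1.98% to 6.23%) and 16.2% (12.6% to 20.3%). Alveolar myofibroblast-like cells made up 3.98% (2.62% to 5.78%), 11.4% (8.24% to 15.2%) and 9.16% (6.43% to 12.6%). Alveolar fibroblast-like cells made up 6.89% (5.07% to 9.11%), 17.3% (13.5% to 21.7%) and 9.70% (6.89% to 13.2%). The 2 plates of male mouse 1 gave 56.4% and 51.6% vascular SMC-like cells. Another 16.4%, 7.10% and 7.28% of cells lay in clusters without a name. At Leiden resolution 2 the airway shares were 0.919%, 1.99% and 0% and the myofibroblast-like shares 14.2%, 17.6% and 18.9%. The sort gate is not known and can set every share, so no test was made between mice.

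**Figure D1:**
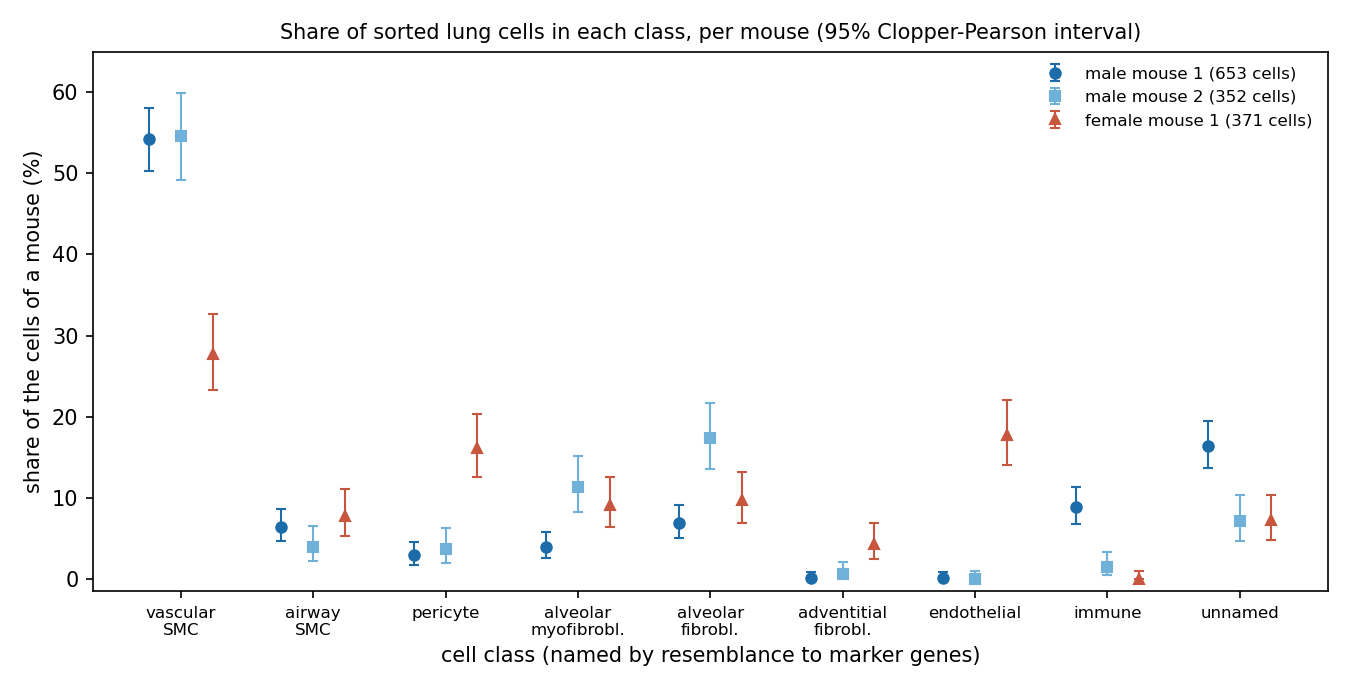
Percent of cells (vertical axis) per class in each of the 3 mice, with exact 95% binomial intervals as error bars. Vascular SMC-like cells are the largest class in each mouse, from 27.8% in female mouse 1 to 54.5% in male mouse 2.

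Airway SMC-like cells had far lower levels of Notch3, Heyl and Hey2 than vascular SMC-like cells and higher levels of Ptch1 and Wnt5a. Notch3, the Notch receptor of mural cells (ENSMUSG00000038146, chromosome 17, 32120820 to 32166852), had 6.44 ± 7.50 against 676 ± 432 CPM in airway against vascular SMC-like cells (log2 fold change −7.16 ± 0.44 (SE, n = 3 mice), adjusted p = 6.62e-06). The Notch target repressors Heyl (log2 fold change −6.25 ± 0.53 (SE, n = 3 mice), adjusted p = 9.06e-05) and Hey2 (−8.14 ± 1.07, adjusted p = 0.00242) were lower as well. Epas1, which encodes the hypoxia-inducible factor HIF-2 alpha (ENSMUSG00000024140, chromosome 17, 86753700 to 86833410), fell with them (24.6 ± 5.89 against 918 ± 213 CPM; log2 fold change −5.15 ± 0.35 (SE, n = 3 mice), adjusted p = 1.65e-05). P2rx1, an ATP-gated cation channel (ENSMUSG00000020787, chromosome 11, 72999103 to 73015200), had 1.42 ± 0.621 against 606 ± 69.0 CPM (log2 fold change −8.94 ± 0.98 (SE, n = 3 mice), adjusted p = 0.000902). Sbspon, which encodes a secreted matrix protein (ENSMUSG00000032719, chromosome 1, 15853862 to 15892722), was higher in airway SMC-like cells (499 ± 85.8 against 5.70 ± 1.76 CPM; log2 fold change 6.62 ± 0.63 (SE, n = 3 mice), adjusted p = 0.000287). Sbspon and Hey2 were not called without male mouse 1 (adjusted p = 0.0566 to 0.0993). Hey2 was not called without male mouse 2 or female mouse 1 (adjusted p = 0.0539 and 0.0904). Notch3, Heyl, Epas1 and P2rx1 kept their calls each time.

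Ptch1, the Hedgehog receptor and a target of the pathway, was higher in airway SMC-like cells (582 ± 197 against 35.8 ± 12.5 CPM; log2 fold change 4.02 ± 0.55 (SE, n = 3 mice), adjusted p = 0.00268), and so were the signalling protein Wnt5a (4.29 ± 0.76, adjusted p = 0.0150) and the R-spondin receptor Lgr5 (61.9 ± 86.0 against 1.07 ± 0.965 CPM; 5.40 ± 0.79, adjusted p = 0.00428). Lgr5 had a count in only 6, 2 and 16 airway SMC-like cells of male mouse 1, male mouse 2 and female mouse 1 and is a leading gene of the myofibroblast cluster, whose markers scored second in the airway cluster. The gap junction protein gene Gja1 (log2 fold change 3.23 ± 0.47 (SE, n = 3 mice), adjusted p = 0.00422), the lung mesenchyme factor Foxf1 (3.14 ± 0.68, adjusted p = 0.0428) and the growth factor Igf1 (4.73 ± 0.85, adjusted p = 0.0157) were higher too. The nitric oxide-sensitive guanylate cyclase subunit Gucy1a1 (log2 fold change −2.10 ± 0.26 (SE, n = 3 mice), adjusted p = 0.00165) and the prostacyclin receptor Ptgir (−7.04 ± 1.10, adjusted p = 0.00697) were lower. Bdkrb1, the bradykinin B1 receptor, was higher (7.09 ± 0.998, adjusted p = 0.00355). Pdgfrb, a receptor for platelet-derived growth factor, was lower (log2 fold change −2.44 ± 0.25 (SE, n = 3 mice), adjusted p = 0.000457), and the matrix genes Eln (−2.67 ± 0.56, adjusted p = 0.0401) and Col18a1 (−5.33 ± 1.003, adjusted p = 0.0208) were lower too. Smim5 and Kcnab1 were called lower on 3 and 2 counts in airway SMC-like cells, against 12477 and 13709 in vascular SMC-like cells, so no fold is given. Gucy1a1, Pdgfrb, Ptch1, Ptgir, Gja1, Bdkrb1, Col18a1, Lgr5, Eln, Igf1, Foxf1 and Wnt5a were not called without male mouse 1 (adjusted p = 0.0637 to 0.302). Bdkrb1, Foxf1 and Eln were not called without male mouse 2 (adjusted p = 0.0717 to 0.110). Bdkrb1, Wnt5a, Gucy1a1, Gja1, Lgr5, Ptgir, Ptch1, Eln, Col18a1, Igf1 and Foxf1 were not called without female mouse 1 (adjusted p = 0.0690 to 0.424).

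Notch pathway genes (17 tested) held 0 higher, 4 lower and 13 not called, or 0 higher and 5 lower adjusted over the list alone. Against all other genes the list leaned lower (adjusted p = 0.000666, or 0.00320 with an estimated correlation), at a median log2 fold change of −0.47 (mean −2.20). Hedgehog and Wnt pathway genes (37 tested) held 5 higher, 0 lower and 32 not called, or 7 higher and 3 lower adjusted over the list alone. As a list they leaned higher (adjusted p = 0.000781, or 0.225 with an estimated correlation), at a median log2 fold change of 0.13 (mean 0.38). Chemokine, cytokine and adhesion genes (35 tested) held 0 higher, 4 lower and 31 not called, or 0 higher and 9 lower adjusted over the list alone. Tested together, these genes leaned lower (adjusted p = 4.81e-05, or 0.0101 with an estimated correlation), at a median log2 fold change of −1.06 (mean −1.77). Vcam1 (−4.03 ± 0.73, adjusted p = 0.0175) and Cxcl12 (−2.96 ± 0.58, adjusted p = 0.0254) were examples that fell. Immediate early and heat shock genes (28 tested) held 6 higher, 0 lower and 22 not called, or 9 higher and 1 lower adjusted over the list alone. Their list test leaned higher (adjusted p = 2.76e-12, or 0.0812 with an estimated correlation), at a median log2 fold change of 0.69 (mean 0.77). Nr4a2 (3.66 ± 0.66, adjusted p = 0.0174) and Zfp36 (1.95 ± 0.37, adjusted p = 0.0231) were among those that rose. Zfp36, Nr4a2, Vcam1 and Cxcl12 were not called in any fit that left out a mouse. Adjusted p was 0.0758 to 0.279 without male mouse 1, 0.0582 to 0.237 without male mouse 2 and 0.102 to 0.186 without female mouse 1. Contractile protein genes (21 tested) held 0 higher and 0 lower, or 0 and 1 adjusted over the list alone (list test adjusted p = 0.973). Lmod1, for example, had 382 ± 38.5 against 570.1 ± 121 CPM (adjusted p = 0.515). Ion channel and calcium genes (27 tested) held 0 higher and 1 lower, or 6 and 3 adjusted over the list alone (list test adjusted p = 0.0575, leaning higher, against a median of 0.12 and a mean of −0.27). Receptors for vasoactive and bronchoactive ligands (39 tested) held 2 higher and 4 lower, or 5 and 6 adjusted over the list alone (list test adjusted p = 0.611). Cyclic nucleotide signalling genes (24 tested) held 2 higher and 1 lower, or 2 and 2 adjusted over the list alone (list test adjusted p = 0.478, leaning higher, against a median of −0.41 and a mean of −0.37). Basement membrane genes (21 tested) held 0 higher and 1 lower, or 0 and 3 adjusted over the list alone (list test adjusted p = 0.989). Fibrillar collagen and elastic fibre genes (39 tested) held 0 higher and 2 lower, or 1 and 4 adjusted over the list alone (list test adjusted p = 0.812). TGF-beta and BMP pathway genes (31 tested) held 1 higher and 0 lower, or 3 and 0 adjusted over the list alone (list test adjusted p = 0.162, leaning higher, against a median of −0.24 and a mean of −0.13). Regional and lineage transcription factors (47 tested) held 3 higher and 3 lower, or 7 and 12 adjusted over the list alone (list test adjusted p = 0.691). Growth factors and their receptors (51 tested) held 5 higher and 4 lower, or 7 and 8 adjusted over the list alone (list test adjusted p = 0.908).

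In all, 223 of 16129 genes passed, 89 higher and 134 lower in airway SMC-like cells (89 and 85 with only these classes in the fit), and 211 remained without naming markers. All genes tested had a median log2 fold change of −0.30. The count fell to 12 without male mouse 1, 86 without male mouse 2 and 30 without female mouse 1, and 9 genes passed in all 3 of these fits. The airway class depends on the clustering, since at Leiden resolution 2 too few cells of some mouse kept the name and no comparison could be made.

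Pericyte-like cells had less of the contractile machinery than vascular SMC-like cells and more Gucy1a1, Gucy1b1 and Pdgfrb. Actg2, a smooth muscle actin (ENSMUSG00000059430, chromosome 6, 83512905 to 83536265), had 319.7 ± 69.2 against 1788 ± 318 CPM in pericyte-like against vascular SMC-like cells (log2 fold change −2.50 ± 0.29 (SE, n = 3 mice), adjusted p = 0.000796), and Myh11, the smooth muscle myosin heavy chain, was lower too (986 ± 391 against 4054 ± 276 CPM; log2 fold change −2.12 ± 0.32 (SE, n = 3 mice), adjusted p = 0.00380). Gucy1a1, a subunit of the nitric oxide-sensitive guanylate cyclase (ENSMUSG00000033910, chromosome 3, 82092427 to 82145789; 4202 ± 1225 against 879 ± 99.3 CPM; log2 fold change 2.24 ± 0.26 (SE, n = 3 mice), adjusted p = 0.000796), and its partner subunit Gucy1b1 (2.55 ± 0.28, adjusted p = 0.000597) were higher. Pde5a, the phosphodiesterase that breaks down cyclic GMP, was higher as well (log2 fold change 3.38 ± 0.34 (SE, n = 3 mice), adjusted p = 0.000379). F2r, the thrombin receptor, was higher (1540.1 ± 610.3 against 201 ± 40.2 CPM; log2 fold change 2.90 ± 0.27 (SE, n = 3 mice), adjusted p = 0.000194), and so was Pdgfrb (ENSMUSG00000024620, chromosome 18, 61045150 to 61085061; log2 fold change 2.20 ± 0.24 (SE, n = 3 mice), adjusted p = 0.000654). Gucy1b1 and Myh11 were not called without male mouse 1 (adjusted p = 0.0582 to 0.0890). Actg2, Gucy1a1, Pde5a, F2r and Pdgfrb kept their calls each time.

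Among transcription factors, Tbx4 (log2 fold change 2.30 ± 0.22 (SE, n = 3 mice), adjusted p = 0.000194), Tbx2 (3.01 ± 0.39, adjusted p = 0.00148) and Tbx5 (1.70 ± 0.35, adjusted p = 0.0218) were higher in pericyte-like cells and Gata6 was lower (−7.59 ± 1.43, adjusted p = 0.0152). The basement membrane collagens Col4a1 (log2 fold change 2.33 ± 0.25 (SE, n = 3 mice), adjusted p = 0.000597) and Col4a2 (2.66 ± 0.42, adjusted p = 0.00488) were higher. Bmp3 was lower (log2 fold change −6.54 ± 0.69 (SE, n = 3 mice), adjusted p = 0.000464) and Bmp4 higher (4.69 ± 0.70, adjusted p = 0.00406), both secreted ligands of the BMP family. The adenylate cyclase Adcy5 was lower (−5.67 ± 0.72, adjusted p = 0.00139) and Adcy8 higher (7.24 ± 1.51, adjusted p = 0.0239). P2rx1 was lower (−7.12 ± 0.90, adjusted p = 0.00139), as was the matrix gene Ltbp1 (−5.07 ± 0.70, adjusted p = 0.00239). Lum, a small matrix proteoglycan, was lower (−3.51 ± 0.62, adjusted p = 0.0106), and at Leiden resolution 2 this sign turned. Adcy5, Tbx2, Ltbp1, Bmp4, Col4a2, Lum, Gata6 and Tbx5 were not called without male mouse 1 (adjusted p = 0.0554 to 0.290). Adcy5, P2rx1, Bmp4, Lum, Ltbp1, Gata6, Adcy8 and Tbx5 were not called without male mouse 2 (adjusted p = 0.0588 to 0.287). Lum, Col4a2, Gata6 and Adcy8 were not called without female mouse 1 (adjusted p = 0.0670 to 0.185). Tbx4, Col4a1 and Bmp3 kept their calls each time.

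Contractile protein genes (21 tested) held 0 higher, 13 lower and 8 not called, or 0 higher and 16 lower adjusted over the list alone. Compared with other genes, the list leaned lower (adjusted p = 1.39e-15, or 0.0193 with an estimated correlation), at a median log2 fold change of −1.64 (mean −1.44). Acta2 is a list member and also the reporter gene, and was among those lower. Immediate early and heat shock genes (28 tested) held 0 higher, 4 lower and 24 not called, or 0 higher and 12 lower adjusted over the list alone. In the list test they leaned lower (adjusted p = 1.80e-06, or 0.236 with an estimated correlation), at a median log2 fold change of −1.05 (mean −1.53). Basement membrane genes (21 tested) held 4 higher, 2 lower and 15 not called, or 6 higher and 3 lower adjusted over the list alone. The test of this list leaned higher (adjusted p = 0.0282, or 0.200 with an estimated correlation), at a median log2 fold change of −0.17 (mean −0.52), which differ in sign from the test or each other, against a median of −0.47 in other genes. Growth factors and their receptors (51 tested) held 2 higher, 10 lower and 39 not called, or 4 higher and 12 lower adjusted over the list alone. Against all other genes the list leaned lower (adjusted p = 0.0282, or 0.225 with an estimated correlation), at a median log2 fold change of −1.33 (mean −1.47). Regional and lineage transcription factors (47 tested) held 4 higher, 1 lower and 42 not called, or 5 higher and 4 lower adjusted over the list alone. As a list they leaned higher (adjusted p = 0.00444, or 0.00682 with an estimated correlation), at a median log2 fold change of 0.12 (mean −0.46), which differ in sign from the test or each other, against a median of −0.47 in other genes. Notch pathway genes (17 tested) held 0 higher, 0 lower and 17 not called, or 2 higher and 0 lower adjusted over the list alone. Tested together, these genes leaned higher (adjusted p = 0.0273, or 0.0553 with an estimated correlation), at a median log2 fold change of 0.41 (mean 0.38). Nrarp had 155 ± 79.8 against 8.41 ± 4.68 CPM (adjusted p = 0.0630) and Notch3 had 1649 ± 1334 against 676 ± 432 CPM (adjusted p = 0.0920). Ion channel and calcium genes (27 tested) held 0 higher and 1 lower, or 1 and 7 adjusted over the list alone (list test adjusted p = 0.0861). Receptors for vasoactive and bronchoactive ligands (39 tested) held 5 higher and 3 lower, or 6 and 8 adjusted over the list alone (list test adjusted p = 0.1802, leaning higher, against a median of −0.51 and a mean of −0.95). Cyclic nucleotide signalling genes (24 tested) held 2 higher and 3 lower, or 2 and 6 adjusted over the list alone (list test adjusted p = 0.523, leaning higher, against a median of 0.28 and a mean of −0.22). Fibrillar collagen and elastic fibre genes (39 tested) held 1 higher and 5 lower, or 6 and 7 adjusted over the list alone (list test adjusted p = 0.763, leaning higher, against a median of −0.20 and a mean of −0.56). Hedgehog and Wnt pathway genes (37 tested) held 4 higher and 0 lower, or 5 and 9 adjusted over the list alone (list test adjusted p = 0.973). TGF-beta and BMP pathway genes (31 tested) held 4 higher and 1 lower, or 4 and 2 adjusted over the list alone (list test adjusted p = 0.0646, leaning higher, against a median of 0.05 and a mean of −0.28). Chemokine, cytokine and adhesion genes (35 tested) held 1 higher and 2 lower, or 4 and 7 adjusted over the list alone (list test adjusted p = 0.763).

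In all, 449 of 16129 genes passed, 159 higher and 290 lower in pericyte-like cells, and 435 remained without naming markers. All genes tested had a median log2 fold change of −0.47. With RLE factors 492 passed (49.4% higher), with DESeq2 1924 (36.3% higher) and with only these classes in the fit 166 (60.2% higher), so the surplus of lower genes depends on the fit. The count fell to 47 without male mouse 1, 104 without male mouse 2 and 179 without female mouse 1, and to 151 without plate 046s. Pericyte-like cells came from a pair of clusters in differing proportions per mouse, with 13, 4 and 29 cells of a Col8a1-high cluster and 6, 9 and 31 of a Clstn2-high cluster in male mouse 1, male mouse 2 and female mouse 1.

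With all 5 classes and 3 mice in the fit, pericyte-like and airway SMC-like cells gave the highest count of genes that passed. Alveolar fibroblast-like against pericyte-like cells gave more with only the compared classes (348 against 203) and without male mouse 2 (387 against 384), and as many without male mouse 1. Notch3 had 1649 ± 1334 against 6.44 ± 7.50 CPM in pericyte-like against airway SMC-like cells (log2 fold change 8.30 ± 0.46 (SE, n = 3 mice), adjusted p = 1.92e-06), and Heyl (log2 fold change 6.65 ± 0.54 (SE, n = 3 mice), adjusted p = 2.29e-05) and Epas1 (log2 fold change 6.29 ± 0.37 (SE, n = 3 mice), adjusted p = 2.51e-06) were higher with it. The transcription factors Ebf1 (6.88 ± 0.82, adjusted p = 0.000443) and Foxs1 (8.25 ± 0.93, adjusted p = 0.000266) were higher too. Pdgfrb had 2965 ± 1579 against 138 ± 128 CPM (log2 fold change 4.64 ± 0.27 (SE, n = 3 mice), adjusted p = 2.51e-06) and Gucy1a1 had 4202 ± 1225 against 201 ± 39.8 CPM (log2 fold change 4.34 ± 0.29 (SE, n = 3 mice), adjusted p = 4.53e-06). Hbegf, a growth factor that binds the EGF receptor, was higher (9.79 ± 1.18, adjusted p = 0.000482), and so was the laminin gene Lamb1 (6.62 ± 1.05, adjusted p = 0.00301). Prss23 (6.74 ± 0.41, adjusted p = 2.51e-06) and the overlapping Prss23os (6.91 ± 0.52, adjusted p = 1.11e-05) were both higher, and reads of one may have been counted for the other. All these genes kept their calls without any one mouse.

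Sbspon (log2 fold change −9.63 ± 0.75 (SE, n = 3 mice), adjusted p = 1.83e-05), Gja1 (log2 fold change −8.44 ± 0.61 (SE, n = 3 mice), adjusted p = 8.58e-06) and the guidance factor Sema3c (−7.79 ± 0.94, adjusted p = 0.000443) were lower in pericyte-like cells. The endothelin receptor gene Ednrb (11.4 ± 10.4 against 1533 ± 422 CPM; log2 fold change −7.01 ± 0.78 (SE, n = 3 mice), adjusted p = 0.000240) and the prostacyclin synthase gene Ptgis (−6.45 ± 0.43, adjusted p = 4.95e-06) were lower. The muscle genes Tcap (−6.77 ± 0.41, adjusted p = 2.51e-06) and Pdlim3 (−8.36 ± 0.79, adjusted p = 7.86e-05) were lower too. Rgs2, a regulator of G protein signalling, was lower (229.5 ± 199.9 against 2042 ± 696 CPM; log2 fold change −3.28 ± 0.41 (SE, n = 3 mice), adjusted p = 0.000677), as was Lgr5 (−5.26 ± 0.84, adjusted p = 0.00295). Lgr5 was not called without male mouse 1 or female mouse 1 (adjusted p = 0.0703 and 0.0584). The others kept their calls each time.

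Contractile protein genes (21 tested) held 0 higher, 15 lower and 6 not called, or 1 higher and 17 lower adjusted over the list alone. Their list test leaned lower (adjusted p = 3.26e-12, or 0.0485 with an estimated correlation), at a median log2 fold change of −1.34 (mean −1.35). Acta2, the reporter gene, was again among those lower. Immediate early and heat shock genes (28 tested) held 0 higher, 15 lower and 13 not called, or 1 higher and 22 lower adjusted over the list alone. Compared with other genes, the list leaned lower (adjusted p = 2.66e-15, or 0.0468 with an estimated correlation), at a median log2 fold change of −2.11 (mean −2.30). Nr4a2 (−8.43 ± 0.84, adjusted p = 0.000127) and Zfp36 (−2.95 ± 0.39, adjusted p = 0.000902) were examples that kept their calls without any one mouse. Notch pathway genes (17 tested) held 5 higher, 0 lower and 12 not called, or 5 higher and 0 lower adjusted over the list alone. In the list test they leaned higher (adjusted p = 5.68e-05, or 0.000573 with an estimated correlation), at a median log2 fold change of 1.29 (mean 2.58). Regional and lineage transcription factors (47 tested) held 7 higher, 3 lower and 37 not called, or 10 higher and 5 lower adjusted over the list alone. The test of this list leaned higher (adjusted p = 0.0171, or 0.0202 with an estimated correlation), at a median log2 fold change of 0.55 (mean 0.74). Hedgehog and Wnt pathway genes (37 tested) held 1 higher, 6 lower and 30 not called, or 4 higher and 13 lower adjusted over the list alone. Against all other genes the list leaned lower (adjusted p = 0.0103, or 0.317 with an estimated correlation), at a median log2 fold change of −1.55 (mean −1.58). Ion channel and calcium genes (27 tested) held 0 higher, 5 lower and 22 not called, or 0 higher and 5 lower adjusted over the list alone. As a list they leaned lower (adjusted p = 0.0282, or 0.225 with an estimated correlation), at a median log2 fold change of −1.58 (mean −1.18). Basement membrane genes (21 tested) held 5 higher, 1 lower and 15 not called, or 7 higher and 3 lower adjusted over the list alone. Tested together, these genes leaned higher (adjusted p = 0.0478, or 0.225 with an estimated correlation), at a median log2 fold change of 0.88 (mean 0.18). Chemokine, cytokine and adhesion genes (35 tested) held 9 higher, 1 lower and 25 not called, or 10 higher and 4 lower adjusted over the list alone. Their list test leaned higher (adjusted p = 0.0282, or 0.200 with an estimated correlation), at a median log2 fold change of 0.42 (mean 0.99). Receptors for vasoactive and bronchoactive ligands (39 tested) held 6 higher and 3 lower, or 10 and 10 adjusted over the list alone (list test adjusted p = 0.141, leaning higher, against a median of 0.44 and a mean of −0.04). Cyclic nucleotide signalling genes (24 tested) held 4 higher and 5 lower, or 5 and 6 adjusted over the list alone (list test adjusted p = 0.763). Fibrillar collagen and elastic fibre genes (39 tested) held 6 higher and 4 lower, or 6 and 6 adjusted over the list alone (list test adjusted p = 0.624). TGF-beta and BMP pathway genes (31 tested) held 2 higher and 3 lower, or 4 and 4 adjusted over the list alone (list test adjusted p = 0.416, leaning higher, against a median of 0.56 and a mean of −0.15). Growth factors and their receptors (51 tested) held 5 higher and 14 lower, or 8 and 18 adjusted over the list alone (list test adjusted p = 0.0646).

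In all, 919 of 16129 genes passed, 421 higher and 498 lower in pericyte-like cells (106 and 97 with only these classes in the fit), and 900 remained without naming markers. All genes tested had a median log2 fold change of −0.10. The count was 225 without male mouse 1, 384 without male mouse 2 and 408 without female mouse 1, and 132 genes passed in all 3 of these fits. It was 530 without plate 046s and 562 with the stricter cell filter.

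**Figure D2:**
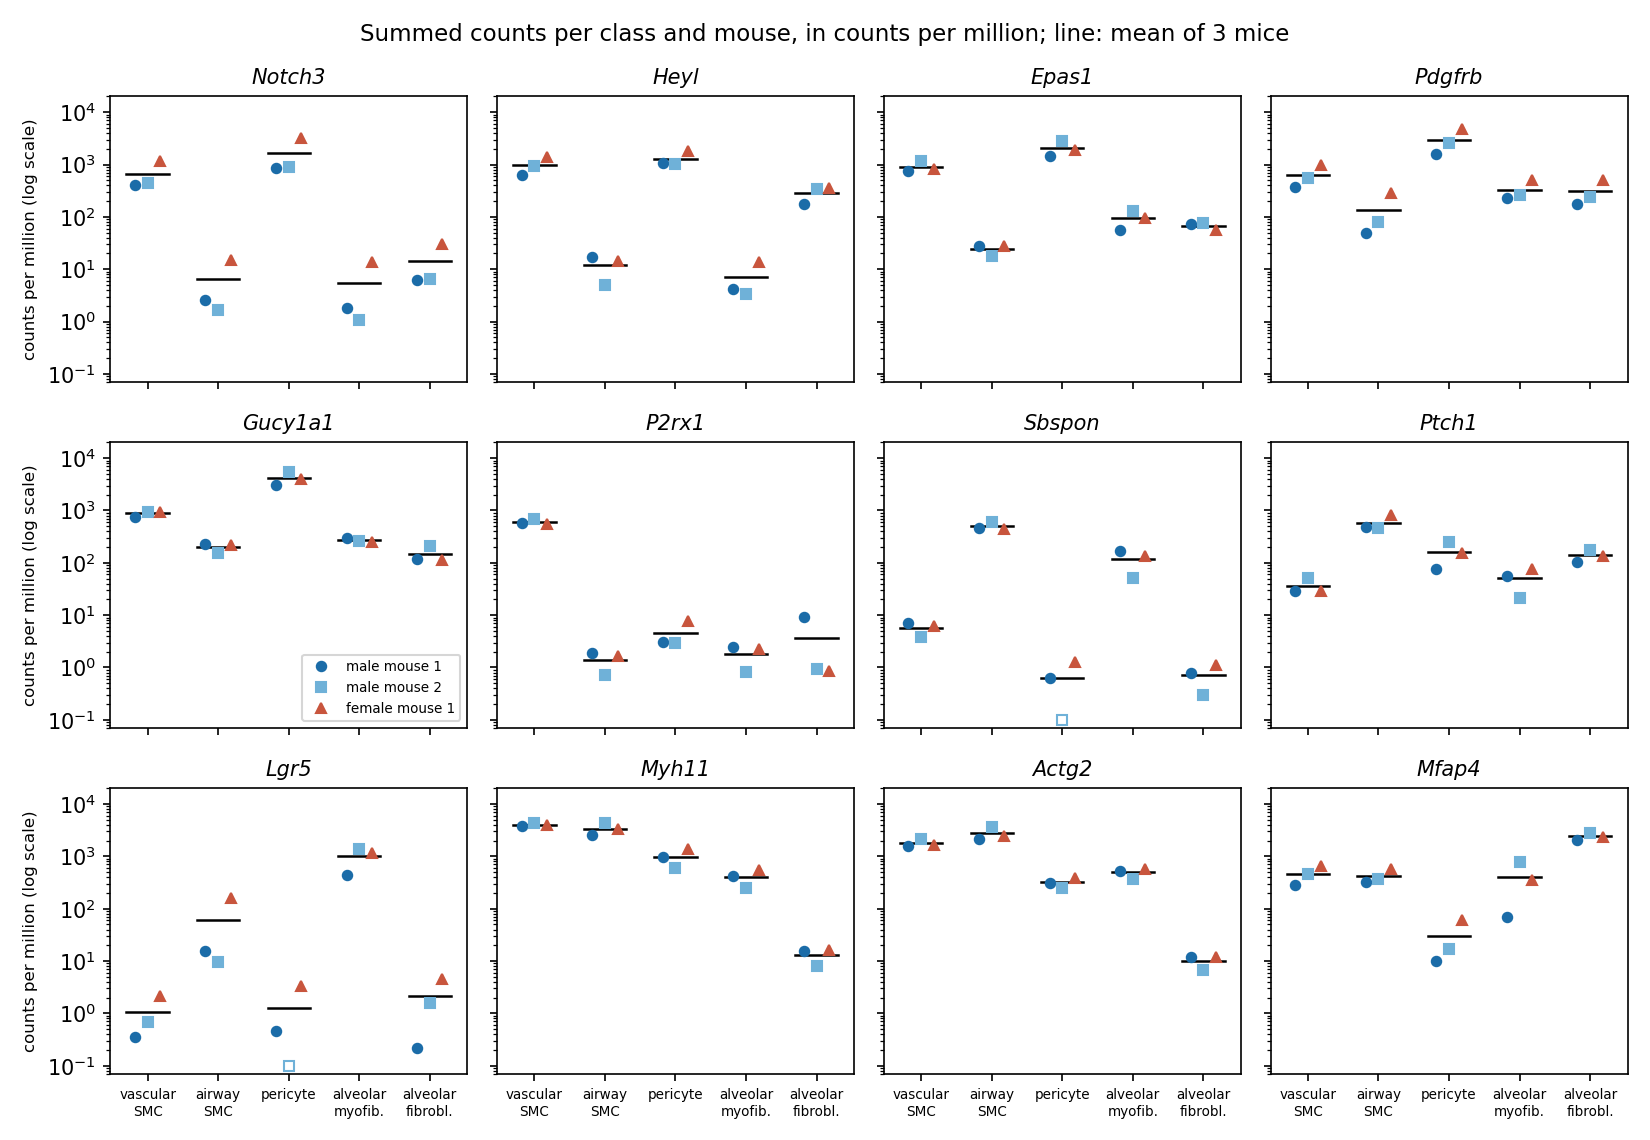
Level of 12 genes in CPM (log axis) per class, with 1 point per mouse. The 2 points under 0.1 CPM are drawn open at that value. Notch3 lies at 1649 CPM on average in pericyte-like cells and 6.44 CPM in airway SMC-like cells.

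Alveolar myofibroblast-like cells had less contractile gene expression and higher levels of Lum, Igfbp3 and Thbs2 than airway SMC-like cells. Myh11 (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372) had 409 ± 151 against 3406 ± 837 CPM in myofibroblast-like against airway SMC-like cells (log2 fold change −3.14 ± 0.33 (SE, n = 3 mice), adjusted p = 0.000754). Kcnmb1, the beta subunit of the large-conductance potassium channel (ENSMUSG00000020155, chromosome 11, 33963013 to 33973641), had 2.78 ± 1.65 against 326 ± 83.8 CPM (log2 fold change −6.92 ± 0.55 (SE, n = 3 mice), adjusted p = 0.000126). Ano1, a calcium-activated chloride channel, was lower too (−7.83 ± 0.97, adjusted p = 0.00259), as was the cyclin gene Ccnd2 (log2 fold change −6.07 ± 0.39 (SE, n = 3 mice), adjusted p = 2.19e-05). Lum (ENSMUSG00000036446, chromosome 10, 97565128 to 97572703; 2142 ± 1468 against 12.8 ± 4.79 CPM; log2 fold change 7.01 ± 0.72 (SE, n = 3 mice), adjusted p = 0.000646), Igfbp3, which binds insulin-like growth factors (5.76 ± 0.71, adjusted p = 0.00259), and the matrix gene Thbs2 (5.61 ± 0.75, adjusted p = 0.00402) were higher. Lum, Myh11, Igfbp3 and Thbs2 were not called without male mouse 1 (adjusted p = 0.0714 to 0.151). Ano1 was not called without male mouse 2 (adjusted p = 0.0623). Thbs2 and Ano1 were not called without female mouse 1 (adjusted p = 0.0716 to 0.0956). Kcnmb1 and Ccnd2 kept their calls each time.

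Lgr5 had 1002 ± 503 against 61.9 ± 86.0 CPM (log2 fold change 4.92 ± 0.78 (SE, n = 3 mice), adjusted p = 0.00965) and Ptch1 had 51.0 ± 27.2 against 582 ± 197 CPM (log2 fold change −3.46 ± 0.53 (SE, n = 3 mice), adjusted p = 0.00943). The BMP ligand gene Bmp5 was higher (3.54 ± 0.41, adjusted p = 0.00200). Pappa2, a protease that acts on an insulin-like growth factor binding protein, was higher (8.23 ± 1.66, adjusted p = 0.0389). Pde5a (−1.80 ± 0.32, adjusted p = 0.0193) and the adhesion gene Mcam (−5.26 ± 0.95, adjusted p = 0.0203) were lower, and Epas1 (1.84 ± 0.31, adjusted p = 0.0152) and F2r (1.57 ± 0.26, adjusted p = 0.0141) were higher. Itgb3 was called lower on 0 counts in myofibroblast-like cells against 434, so no fold is given. Epas1, Ptch1, Lgr5, F2r, Pde5a, Mcam and Pappa2 were not called without male mouse 1 (adjusted p = 0.131 to 0.350). Lgr5, Pappa2, Epas1, Mcam, F2r and Pde5a were not called without male mouse 2 (adjusted p = 0.0677 to 0.247). Bmp5, Pde5a, Lgr5, F2r, Ptch1, Epas1 and Pappa2 were not called without female mouse 1 (adjusted p = 0.0716 to 0.282).

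Contractile protein genes (21 tested) held 0 higher, 14 lower and 7 not called, or 0 higher and 21 lower adjusted over the list alone. Compared with other genes, the list leaned lower (adjusted p = 1.43e-35, or 0.000527 with an estimated correlation), at a median log2 fold change of −1.55 (mean −1.77). Acta2, the reporter gene, was among those lower. Ion channel and calcium genes (27 tested) held 0 higher, 3 lower and 24 not called, or 0 higher and 7 lower adjusted over the list alone. In the list test they leaned lower (adjusted p = 3.70e-06, or 0.00682 with an estimated correlation), at a median log2 fold change of −1.25 (mean −2.24). Fibrillar collagen and elastic fibre genes (39 tested) held 6 higher, 0 lower and 33 not called, or 9 higher and 0 lower adjusted over the list alone. The test of this list leaned higher (adjusted p = 2.75e-11, or 0.0138 with an estimated correlation), at a median log2 fold change of 0.81 (mean 1.21). Col3a1 was an example that rose (6475 ± 2469 against 2469 ± 1651 CPM; 1.54 ± 0.25, adjusted p = 0.0136). Col3a1 was not called without male mouse 1, male mouse 2 or female mouse 1 (adjusted p = 0.154, 0.194 and 0.0716). Cyclic nucleotide signalling genes (24 tested) held 0 higher, 1 lower and 23 not called, or 1 higher and 5 lower adjusted over the list alone. Against all other genes the list leaned lower (adjusted p = 0.0423, or 0.296 with an estimated correlation), at a median log2 fold change of −0.23 (mean −0.53). Immediate early and heat shock genes (28 tested) held 0 higher, 0 lower and 28 not called, or 0 higher and 8 lower adjusted over the list alone. As a list they leaned lower (adjusted p = 2.39e-06, or 0.239 with an estimated correlation), at a median log2 fold change of −0.55 (mean −0.79). Receptors for vasoactive and bronchoactive ligands (39 tested) held 1 higher and 0 lower, or 1 and 3 adjusted over the list alone (list test adjusted p = 0.787). Basement membrane genes (21 tested) held 0 higher and 0 lower, or 0 and 3 adjusted over the list alone (list test adjusted p = 0.265). Notch pathway genes (17 tested) held 0 higher and 0 lower, or 0 and 0 adjusted over the list alone (list test adjusted p = 0.197). Hedgehog and Wnt pathway genes (37 tested) held 1 higher and 1 lower, or 2 and 4 adjusted over the list alone (list test adjusted p = 0.353). TGF-beta and BMP pathway genes (31 tested) held 1 higher and 0 lower, or 3 and 1 adjusted over the list alone (list test adjusted p = 0.563). Regional and lineage transcription factors (47 tested) held 1 higher and 0 lower, or 2 and 0 adjusted over the list alone (list test adjusted p = 0.973). Growth factors and their receptors (51 tested) held 2 higher and 0 lower, or 5 and 4 adjusted over the list alone (list test adjusted p = 0.192). Chemokine, cytokine and adhesion genes (35 tested) held 0 higher and 4 lower, or 6 and 8 adjusted over the list alone (list test adjusted p = 0.812, leaning lower, against a median of 0.39 and a mean of −0.37).

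In all, 159 of 16129 genes passed, 75 higher and 84 lower in myofibroblast-like cells, and 149 remained without naming markers. All genes tested had a median log2 fold change of 0.08. The count fell to 5 without male mouse 1, 32 without male mouse 2 and 29 without female mouse 1, to 71 with no mouse block and to 9 with only these classes in the fit.

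Alveolar fibroblast-like cells had more elastic fibre and collagen genes and less contractile gene expression than pericyte-like cells. Mfap4, which encodes a protein of elastic fibres (ENSMUSG00000042436, chromosome 11, 61485431 to 61488900), had 2438 ± 384 against 29.5 ± 27.7 CPM in alveolar fibroblast-like against pericyte-like cells (log2 fold change 6.66 ± 0.73 (SE, n = 3 mice), adjusted p = 0.000214), and Col1a2 had 3661 ± 1341 against 1279 ± 539.7 CPM (log2 fold change 1.55 ± 0.19 (SE, n = 3 mice), adjusted p = 0.000411). Slc36a2, an amino acid transporter (ENSMUSG00000020264, chromosome 11, 55158470 to 55185077), was higher (log2 fold change 9.80 ± 0.86 (SE, n = 3 mice), adjusted p = 3.53e-05). Bmp3 (ENSMUSG00000029335, chromosome 5, 98854415 to 98884396; log2 fold change 7.11 ± 0.70 (SE, n = 3 mice), adjusted p = 9.13e-05) and its relative Gdf10 (8.39 ± 1.19, adjusted p = 0.00130) were higher. The growth factor Vegfd (7.62 ± 0.97, adjusted p = 0.000612), the guidance factor Slit2 (8.60 ± 0.97, adjusted p = 0.000263) and Wnt2 (9.36 ± 1.45, adjusted p = 0.00210) were higher too. Of the 10 genes with the largest rise, 6 were Ugt1a genes with near-identical values, which share sequence and are not separate findings. Wnt2 was not called without male mouse 1 or male mouse 2 (adjusted p = 0.0657 and 0.0517). Mfap4, Col1a2, Slc36a2, Bmp3, Gdf10, Vegfd and Slit2 kept their calls each time.

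Notch3 (log2 fold change −7.02 ± 0.43 (SE, n = 3 mice), adjusted p = 2.59e-06), Pdgfrb (log2 fold change −3.28 ± 0.25 (SE, n = 3 mice), adjusted p = 2.12e-05) and Epas1 (log2 fold change −4.86 ± 0.35 (SE, n = 3 mice), adjusted p = 1.06e-05) were lower in alveolar fibroblast-like cells. Gucy1b1 had 24.2 ± 18.6 against 1575 ± 927 CPM (log2 fold change −6.13 ± 0.33 (SE, n = 3 mice), adjusted p = 1.75e-06) and Pde5a was lower (−4.57 ± 0.36, adjusted p = 2.17e-05). Mcam, which encodes the adhesion protein CD146, was lower (−9.00 ± 1.07, adjusted p = 0.000408), as were Myh11 (−6.19 ± 0.38, adjusted p = 2.59e-06) and Kcnmb1 (−6.25 ± 0.54, adjusted p = 3.53e-05). Heyl was lower by a smaller fold (−2.11 ± 0.44, adjusted p = 0.0134). Plcxd3 and Adcy8 were called on 2 counts each in the class with fewer, Plcxd3 higher and Adcy8 lower, so no folds are given. Heyl was not called without male mouse 1 or female mouse 1 (adjusted p = 0.108 and 0.133). Notch3, Pdgfrb, Epas1, Gucy1b1, Pde5a, Mcam, Myh11 and Kcnmb1 kept their calls each time.

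Contractile protein genes (21 tested) held 1 higher, 17 lower and 3 not called, or 1 higher and 18 lower adjusted over the list alone. Tested together, these genes leaned lower (adjusted p = 4.15e-30, or 0.000717 with an estimated correlation), at a median log2 fold change of −1.74 (mean −2.34). Acta2, the reporter gene, was among those lower. Fibrillar collagen and elastic fibre genes (39 tested) held 19 higher, 1 lower and 19 not called, or 26 higher and 1 lower adjusted over the list alone. Their list test leaned higher (adjusted p = 2.76e-12, or 0.00992 with an estimated correlation), at a median log2 fold change of 1.55 (mean 2.02). Notch pathway genes (17 tested) held 0 higher, 4 lower and 13 not called, or 0 higher and 5 lower adjusted over the list alone. Compared with other genes, the list leaned lower (adjusted p = 5.42e-05, or 0.000573 with an estimated correlation), at a median log2 fold change of −0.78 (mean −1.74). Immediate early and heat shock genes (28 tested) held 8 higher, 0 lower and 20 not called, or 16 higher and 0 lower adjusted over the list alone. In the list test they leaned higher (adjusted p = 1.08e-09, or 0.142 with an estimated correlation), at a median log2 fold change of 1.32 (mean 1.92). Regional and lineage transcription factors (47 tested) held 2 higher, 9 lower and 36 not called, or 3 higher and 11 lower adjusted over the list alone. The test of this list leaned lower (adjusted p = 0.000847, or 0.00161 with an estimated correlation), at a median log2 fold change of −0.64 (mean −0.54). Growth factors and their receptors (51 tested) held 14 higher, 5 lower and 32 not called, or 21 higher and 7 lower adjusted over the list alone. Against all other genes the list leaned higher (adjusted p = 0.00227, or 0.0817 with an estimated correlation), at a median log2 fold change of 2.03 (mean 2.17). Cyclic nucleotide signalling genes (24 tested) held 2 higher, 6 lower and 16 not called, or 3 higher and 8 lower adjusted over the list alone. As a list they leaned lower (adjusted p = 0.000666, or 0.0812 with an estimated correlation), at a median log2 fold change of −1.05 (mean −1.57). Hedgehog and Wnt pathway genes (37 tested) held 5 higher, 1 lower and 31 not called, or 10 higher and 1 lower adjusted over the list alone. Tested together, these genes leaned higher (adjusted p = 0.0234, or 0.381 with an estimated correlation), at a median log2 fold change of 1.36 (mean 2.00). Ion channel and calcium genes (27 tested) held 0 higher, 3 lower and 24 not called, or 2 higher and 7 lower adjusted over the list alone. Their list test leaned lower (adjusted p = 0.0282, or 0.225 with an estimated correlation), at a median log2 fold change of −0.09 (mean −0.49). Receptors for vasoactive and bronchoactive ligands (39 tested) held 6 higher and 7 lower, or 13 and 11 adjusted over the list alone (list test adjusted p = 0.353, leaning lower, against a median of 1.26 and a mean of 0.57). Basement membrane genes (21 tested) held 2 higher and 1 lower, or 4 and 4 adjusted over the list alone (list test adjusted p = 0.868, leaning lower, against a median of 0.41 and a mean of 0.83). TGF-beta and BMP pathway genes (31 tested) held 5 higher and 3 lower, or 5 and 3 adjusted over the list alone (list test adjusted p = 0.893, leaning lower, against a median of 0.01 and a mean of 0.32). Chemokine, cytokine and adhesion genes (35 tested) held 7 higher and 8 lower, or 13 and 9 adjusted over the list alone (list test adjusted p = 0.893).

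In all, 849 of 16129 genes passed, 552 higher and 297 lower in alveolar fibroblast-like cells, and 828 remained without naming markers. All genes tested had a median log2 fold change of 0.32. The count was 225 without male mouse 1, 387 without male mouse 2 and 394 without female mouse 1, and 139 genes passed in all 3 of these fits. It was 433 without plate 046s, 549 with the stricter cell filter and 348 with only these classes in the fit.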

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

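The test for reads counted once per position and the splits of the sums were planned before their results were seen, and the tests of the few-gene cluster and of the endothelial-like and immune-like cells were chosen only after those cells had been seen. The items here are cells that no comparison used, and they were picked out because they lie above the limit that a count of 0 allows. Endothelial-like cells made up 17.8% of female mouse 1 (66 cells), against 1 cell of male mouse 1 and 0 of 352 cells of male mouse 2, which allows a share of up to 0.852%. Immune-like cells, with leading genes C1qc, C1qa and Cx3cr1, made up 8.88% of male mouse 1 (58 cells) and 1.42% of male mouse 2, against 0 of 371 cells of female mouse 1, which allows a share of up to 0.809%. Adventitial fibroblast-like cells made up 4.31% of female mouse 1, a share that depends on the clustering (at resolution 0.5, 11.3% there, 4.29% of male mouse 1 and 5.68% of male mouse 2). The immune-like cluster also scored 1.29 for epithelial markers, and one held-out clustering gave 41 immune-like cells, 40 of them from male mouse 1, in a cluster without that second score. A cluster without a name held 88 cells, of which 80 came from male mouse 1, and another without a name held 71 cells with leading genes Bmp7, Adh7 and Lamc3.

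The endothelial-like and immune-like cells could be wells that also held a smooth muscle cell, or free RNA read as cells. Contractile genes stood at 6.03% of the vascular SMC-like level in the endothelial-like cells and 5.22% in the immune-like cells, which speaks against a muscle cell in most of these wells. An epithelial cell or its RNA in the immune-like wells was not tested. Their own markers reached at most 1.08% of their level in any other named class of the same mouse, so little of their RNA was seen in those wells. The same markers named the clusters, so low levels in other classes are partly built in, and clusters without a name were not part of this check. Wells that held only free RNA are thus not excluded. A gate that differed between the plates of male mouse 1 was left open, as the immune-like share was 7.74% on plate 045s and 10.2% on plate 046s, a difference of −2.46 percentage points (−9.00 to 4.02). Mouse, plate and gate cannot be told apart for the differences between mice. Sex cannot account for the immune-like gap between the males and otherwise stays open. No biological explanation was tested.

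The unnamed cluster of 88 cells could be several cells in 1 well, or damaged cells and free RNA. Its 80 cells in male mouse 1 had a median of 2607 genes against 4405 in that mouse's other cells, a ratio of 0.592, which speaks against several cells in 1 well. They also had 4.09% mitochondrial counts against 1.60%, and a median of 136672 counts against 283456. With equal numbers of cells, the cluster's profile correlated across 10555 genes at 0.505 with a mixture of other cells and at 0.519 with vascular SMC-like cells, a difference of −0.0138 (−0.0477 to 0.0189 over 500 draws), so free RNA or damage stays open. A first version with unequal numbers gave 0.0164 and was replaced after its value had been seen, because a mean over more cells is smoother, and genes are not independent replicates.

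Counts per exonic base stayed low in every cell, which could come from reads at the same position having been counted once before deposit. In vascular SMC-like cells the median slope of log count on log cell total was 0.840 in the genes with the highest counts per base and 0.998 in longer genes of like mean count, a difference of −0.158 over 25 pairs (−0.339 to −0.0241). That is in line with such a step, which the labels do not record, and it would compress the highest levels. No biological explanation was tested.

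The 6 sums of each comparison can be split into 3 and 3 in 10 ways, of which 4 part the sums of every mouse. With only the compared classes in the fit, the real split called 174 genes for airway against vascular SMC-like, 166 for pericyte against vascular SMC-like, 203 for pericyte against airway SMC-like, 9 for alveolar myofibroblast against airway SMC-like and 348 for alveolar fibroblast against pericyte-like cells. It called 20, 6 and 112 genes in the vascular cluster comparisons of 1 against 2, 1 against 3 and 3 against 2. The highest other split called 0 genes in each, so 1 split, the real one, gave as large a count, and 10 splits are too few for a share under 0.05.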

How the results depend on the processing

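The fit without 2 vascular clusters and all vascular cluster comparisons were chosen only after the data had been seen, and every other alternative was fixed before the data were examined. The sign of every named call stayed the same in every setting except that of Lum in pericyte against vascular SMC-like cells, which had a log2 fold change of 1.05 (adjusted p = 0.339) at Leiden resolution 2 against −3.51 (adjusted p = 0.0106). Counts of genes moved far more, and no cause of this was tested. In the order airway against vascular SMC-like, pericyte against vascular SMC-like, pericyte against airway SMC-like, myofibroblast against airway SMC-like and alveolar fibroblast against pericyte-like cells, DESeq2 called 997, 1924, 2793, 1331 and 2410 genes, and each cell scaled to the same total gave 565, 1377, 1704, 425 and 1651. With a mouse left out the counts ranged from 12 to 86, 47 to 179, 225 to 408, 5 to 32 and 225 to 394, in fits with 2 mice. With only the compared classes in the fit, which leaves 6 sums, the last 4 comparisons gave 166, 203, 9 and 348. Without the mouse block, airway against vascular SMC-like gave 134, pericyte against vascular SMC-like 278 and myofibroblast against airway SMC-like 71. Pericyte against vascular SMC-like, pericyte against airway SMC-like and alveolar fibroblast against pericyte-like gave 148, 562 and 549 with the stricter cell filter, which leaves fewer cells, and 151, 530 and 433 without plate 046s. Leiden resolution 2 gave 799 for pericyte against vascular SMC-like. RLE factors, no filter on low counts, classes from all variable genes, another random split of the genes, the fit without plate 045s and the fit without 2 vascular clusters stayed within 1.5 times for these 5 comparisons. Leiden resolution 0.5 gave no comparison with pericyte-like cells and resolution 2 none with airway SMC-like cells. The 2 planned comparisons of adventitial fibroblast-like cells were not run. For vascular clusters 1 against 2, 1 against 3 and 3 against 2, DESeq2 gave 965, 408 and 1439 genes, no block 32, 12 and 155, only the compared clusters 20, 6 and 112, and a left-out mouse 0 to 10, 0 to 2 and 12 to 26. No filter on low counts gave 150 and 44 for the first and second of these.

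With an estimated correlation, 20 list calls were lost. Adjusted p became 0.225 for Hedgehog and Wnt and 0.0812 for immediate early genes in airway against vascular SMC-like cells, and 0.200 for basement membrane, 0.0553 for Notch, 0.225 for growth factors and 0.236 for immediate early genes in pericyte against vascular SMC-like cells. It became 0.225 for ion channels, 0.225 for basement membrane, 0.317 for Hedgehog and Wnt and 0.200 for chemokines in pericyte against airway SMC-like cells, and 0.296 for cyclic nucleotide and 0.239 for immediate early genes in myofibroblast against airway SMC-like cells. In alveolar fibroblast against pericyte-like cells it became 0.225 for ion channels, 0.0812 for cyclic nucleotide, 0.381 for Hedgehog and Wnt, 0.0817 for growth factor and 0.142 for immediate early genes. Among vascular clusters it became 0.606 for contractile proteins in 1 against 3, and 0.152 for fibrillar collagens and 0.0860 for immediate early genes in 3 against 2.

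Shares moved with the clustering. At resolution 0.5, adventitial fibroblast-like cells made up 4.30%, 4.28%, 4.29%, 5.68% and 11.3% of plate 045s, plate 046s, male mouse 1, male mouse 2 and female mouse 1, and unnamed cells 14.04%, 10.5%, 12.4%, 2.27% and 0.270%. At resolution 2 the same order gave airway SMC-like shares of 0.860%, 0.987%, 0.919%, 1.99% and 0%, myofibroblast-like shares of 12.6%, 16.1%, 14.2%, 17.6% and 18.9%, and unnamed shares of 13.8%, 10.5%, 12.3%, 1.99% and 0.270%. Resolution 2 also gave adventitial fibroblast-like shares of 1.43% on plate 045s, 1.53% in male mouse 1, 2.84% in male mouse 2 and 12.7% in female mouse 1, alveolar fibroblast-like shares of 9.46% on plate 045s and 9.95% in male mouse 1, and vascular SMC-like shares of 49.2% in male mouse 1 and 21.3% in female mouse 1. The stricter cell filter gave unnamed shares of 13.6% on plate 045s, 9.30% on plate 046s and 11.6% in male mouse 1, vascular SMC-like shares of 58.4% in male mouse 1 and 48.3% in male mouse 2, and an alveolar fibroblast-like share of 23.4% in male mouse 2. Sums with the fewest cells limit the depth, at 1812315 counts for pericyte-like cells of male mouse 2.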

Other observations

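The comparisons of vascular clusters here, and the look at naming markers in them, were chosen only after the clusters had been seen. No other test in this part was so chosen. In each of the 2 held-out clusterings vascular SMC-like cells fell into 3 clusters, which were compared in the same way. Clusters 1, 2 and 3 held 324, 167 and 150 cells in one of these and 305, 144 and 194 in the other. Cluster 3, led by Efhd1 and Sfrp2, had more contractile gene expression and less Fbln1 and Lum than cluster 2, led by Osr2 and Chrdl1. Fbln1, a matrix glycoprotein gene, had 6.46 ± 7.25 against 636 ± 521 CPM in cluster 3 against cluster 2 (log2 fold change −6.95 ± 0.34 (SE, n = 3 mice), adjusted p = 0.000468). Smtn, a smooth muscle cytoskeletal gene, was higher (1.95 ± 0.25, adjusted p = 0.0110), as was P2rx1 (3.25 ± 0.39, adjusted p = 0.00883), and the transcription factor Tbx4 was lower (−3.22 ± 0.35, adjusted p = 0.00711). Of 6 naming markers of adventitial fibroblasts, Dcn (13.7 ± 2.82 against 336 ± 99.0 CPM; −4.59 ± 0.35, adjusted p = 0.00215), Dpt (−7.16 ± 0.43, adjusted p = 0.00105), Serpinf1 (−7.32 ± 0.88, adjusted p = 0.00861) and Col14a1 (−1.86 ± 0.26, adjusted p = 0.0152) were lower in cluster 3, and Pi16 (adjusted p = 0.857) and Clec3b (adjusted p = 0.106) did not pass. The vascular marker score of cluster 2 was 0.477 and 0.528 in these clusterings, against 0.978 to 1.79 for clusters 1 and 3. Whether fibroblasts, mixed wells or a state of muscle cells underlie the contractile difference was not tested. Genes of contractile proteins (21 tested) held 12 higher, 0 lower and 9 not called, or 20 higher and 0 lower adjusted over the list alone. Compared with other genes, the list leaned higher (adjusted p = 7.62e-25, or 0.00770 with an estimated correlation), at a median log2 fold change of 0.80 (mean 0.91). Genes of fibrillar collagens and elastic fibres (38 tested) held 1 higher, 4 lower and 33 not called, or 6 higher and 6 lower adjusted over the list alone. In the list test they leaned lower (adjusted p = 0.0180, or 0.152 with an estimated correlation), at a median log2 fold change of −0.37 (mean −0.97). Ion channels (adjusted p = 0.0282 and 0.0167 with the preset and the estimated correlation) and immediate early genes (adjusted p = 0.0129 and 0.0860) leaned higher, and transcription factors (adjusted p = 0.0180 and 0.00770) lower. In all, 271 of 14666 genes passed, 138 higher and 133 lower, and 12 to 26 did so when a mouse was left out. Dcn, Tbx4, Smtn, Col14a1 and Serpinf1 were not called without male mouse 1 (adjusted p = 0.0597 to 0.152). Serpinf1, Tbx4, P2rx1 and Col14a1 were not called without male mouse 2 (adjusted p = 0.0918 to 0.171). Dcn, Tbx4, Smtn, Col14a1 and P2rx1 were not called without female mouse 1 (adjusted p = 0.0541 to 0.0989). Fbln1 and Dpt kept their calls each time.

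Cluster 1, with Stac and Kcna5 among its leading genes, differed from cluster 2 in 97 genes, 64 higher and 33 lower. With only these clusters in the fit it was 20, 5 higher and 15 lower. Tcap, a muscle sarcomere gene, was higher (379.8 ± 99.0 against 42.8 ± 18.3 CPM; log2 fold change 3.19 ± 0.20 (SE, n = 3 mice), adjusted p = 0.00261) and Fbln1 lower (−6.70 ± 0.34, adjusted p = 0.00110). The fibroblast markers Dcn (−4.41 ± 0.34, adjusted p = 0.00477), Dpt (−5.41 ± 0.39, adjusted p = 0.00397), Serpinf1 (−7.06 ± 0.87, adjusted p = 0.0202) and Col14a1 (−4.10 ± 0.29, adjusted p = 0.00330) were lower here too, Pi16 (adjusted p = 0.980) and Clec3b (adjusted p = 0.419) did not pass, and the same explanations stay open. Genes of contractile proteins (21 tested) held 5 higher, 0 lower and 16 not called, or 20 higher and 0 lower adjusted over the list alone. The test of this list leaned higher (adjusted p = 2.66e-25, or 0.00770 with an estimated correlation), at a median log2 fold change of 0.71 (mean 0.79). With both correlations, immediate early and heat shock genes (adjusted p = 1.07e-08 and 0.000127) and ion channels (adjusted p = 0.0177 and 0.00770) leaned higher too. Fibrillar collagens (adjusted p = 3.01e-09 and 0.000203) and Hedgehog and Wnt pathways (adjusted p = 0.000196 and 6.15e-05) leaned lower. Stress of dissociation was not tested as a cause. Tcap, Col14a1, Dpt, Dcn and Serpinf1 were not called without male mouse 1 (adjusted p = 0.0548 to 0.244). These and Fbln1 were not called without male mouse 2 (adjusted p = 0.0846 to 0.206). Serpinf1 and Dcn were not called without female mouse 1 (adjusted p = 0.0608 to 0.0968). The count was 4 without male mouse 1, 0 without male mouse 2 (edgeR quasi-likelihood test; 1084 genes had an unadjusted p under 0.05) and 10 without female mouse 1.

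Cluster 1 against cluster 3 gave 23 genes, 14 higher and 9 lower. Thbs1, a matricellular glycoprotein gene, was higher (1572 ± 646 against 237 ± 74.7 CPM; log2 fold change 2.69 ± 0.17 (SE, n = 3 mice), adjusted p = 0.00265) and the secreted Wnt modulator gene Sfrp2 was lower (−4.58 ± 0.33, adjusted p = 0.00397). Genes of fibrillar collagens and elastic fibres (38 tested) held 0 higher, 2 lower and 36 not called, or 1 higher and 9 lower adjusted over the list alone. Against all other genes the list leaned lower (adjusted p = 0.000196, or 0.0167 with an estimated correlation), at a median log2 fold change of −0.24 (mean −0.11). Hedgehog and Wnt genes (adjusted p = 0.000196 and 6.15e-05 with both correlations) and contractile genes (adjusted p = 0.0180 and 0.606) leaned lower, and receptors (adjusted p = 0.00599 and 0.00320), transcription factors (adjusted p = 0.0229 and 0.00985) and immediate early genes (adjusted p = 0.00277 and 0.0373) higher. Sfrp2 was not called without male mouse 1 (adjusted p = 0.130). Thbs1 and Sfrp2 were not called without male mouse 2 (adjusted p = 0.0922 to 0.150). Sfrp2 and Thbs1 were not called without female mouse 1 (adjusted p = 0.0654). The edgeR quasi-likelihood count was 0 without male mouse 2 and 0 without female mouse 1, where 860 and 834 genes had an unadjusted p under 0.05. With all 3 mice, DESeq2 called 408 genes. Cluster 1 held 209, 89 and 26 cells of male mouse 1, male mouse 2 and female mouse 1 in one held-out clustering and 194, 71 and 40 in the other. The clustering on all variable genes served in these tests only to pair the clusters of the held-out clusterings. It also set apart a vascular cluster with 3, 0 and 41 cells of these mice. Another held 44, 24 and 0 cells, with a median of 149721.5 counts per cell.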
